A study of Brassica napus with 27 samples.

How the data were processed

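RNA was sequenced from leaves of wild-type Westar oilseed rape and of 2 lines mutant in FAH genes, in long days and 1 day and 2 days after transfer to short days. There were 9 groups of 3 libraries, and samples were grouped by the genotype, stage and replicate in their labels. Per the labels, RNA was extracted with TRIzol, libraries were made with the TruSeq v2 kit and sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, reads were trimmed with Trim Galore and aligned with HISAT2. Their versions, the genome build and the counting tool are not given in the sources used here. The table of counts per gene was made by the authors and is used as deposited, not scaled to library size. The FPKM table (fragments per kilobase-and-million) was also made by the authors, by a method that is not stated, and was used here only as a check.

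The count table held 119533 entries, 1 of which names no gene and was left out. Of the 119532 gene entries, 29131 were 0 in all libraries. Gene identifiers were matched to a RefSeq gene table of the Da-Ae assembly, which gave 85927 matches and names for 482 genes, and 231 organelle genes are named in the file itself. The other genes are given by count, and no name was inferred. Total counts ranged from 49700646 to 58862542 per library. Plastid-encoded genes took 0.00622% to 0.0230% of counts, mitochondrial genes 0.00260% to 0.0114%, and the 10 most counted genes 3.45% to 7.66%. Between replicates of a group the correlation of log2 counts-per-million was 0.883 to 0.957, and the chi-square per gene of 21.2 to 181 lies far above counting noise, so depth sets the precision only of low counts. Of counts from 1 to 9, 49.3% were even numbers against 44.4% of an even spread. The 71967 symbols in both tables had rank correlations of 0.955 to 0.962 between counts and FPKM within a library, and 100% of the genes called for the double line against wild type at SD2 had the same sign in FPKM, with a pseudocount of 0.1.

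Genes were tested in R 4.3.3 with edgeR 4.0.16. The filter by group kept 72039 genes, 477 of them named and 412 of these nuclear. TMM factors ran from 0.862 to 1.14. One quasi-likelihood fit with robust dispersions held all 27 libraries, with 18 residual degrees of freedom and a common coefficient of biological variation of 0.399. There were 15 contrasts: each line against wild type and the lines against each other at each stage, wild-type SD1 and SD2 against LD, and the differences of each line's SD1 and SD2 changes from those of wild type. All adjusted p-values for genes are edgeR adjusted p-values, Benjamini-Hochberg over the tested genes of a contrast, with a threshold of 0.05, unless another tool is named. Values in CPM are counts-per-million on TMM-scaled library sizes, as mean ± SD of 3 libraries, and errors of fold changes are standard errors. For a gene at 0 in every library of a group, the fold is a bound from 3 counts per library.

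Gene groups were tested with camera in limma 3.58.1 on log2 CPM, with a preset correlation of 0.01, at least 5 members and p-values adjusted over the 24 groups of a contrast. Of 23 lists fixed before the data were examined, 1 had enough members, since few genes carry names, and the members of smaller lists are given singly. The lists for tyrosine degradation, chlorophyll synthesis, nuclear photosystem and Rubisco genes, reactive oxygen scavenging, oxidative stress, autophagy, carbon starvation, the clock and photoperiod, chloroplast ribosomal proteins, the cell cycle, epidermis and guard cells, and root, flower and pollen markers held 0 tested named genes. The other 23 groups tested are families drawn up from names alone, but in the step that first showed the fold changes of named genes. The 4 organelle families were added after that, and the amino acid transporter family and the removal of aap1 from the floral list were corrected after results were seen. The phenylpropanoid family and the anthocyanin list share members.

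Named genes follow a rule written beforehand: per comparison the 5 higher and 5 lower named genes of largest fold change with adjusted p under 0.05, at least 5 CPM in the higher group and no overlap between the 3 and 3 libraries (which chance gives for 10% of genes), and per list up to 3 members of smallest adjusted p with members needed as examples. The catalase gene, cry1, cry2, RGA, Ann1 and AGL20 were chosen after their values were seen, as were the 2 unnamed genes of the single line's SD1 change. FAH results are not reported here.

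Along the Da-Ae gene order, 55439 tested genes were placed and 16600 were not. Unless said otherwise, counts of called genes outside the runs include genes that were not placed. Medians of log2 fold change over windows of 41 genes were taken in LD, and runs kept at a median beyond 0.6 over at least 21 genes, which gave 2059 genes in any run and 1724 in runs of the single line. The threshold was raised and the shortest run set after the first output was seen. Medians per library used a pseudocount of 0.5 CPM and genes with at least 1 CPM in wild type. The covariance and correlation of the lines' fold changes were set against 5 simulations of unchanged groups per stage. The simulated groups had at most 0.2 calls on average, so they give no value for shared calls.

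The steps were tested on simulated data with 200 changed genes. The main test called 10% of genes changed 2-fold and 80% of those changed 4-fold, with 2 false among 94 calls and 0 calls where nothing was changed. DESeq2 on 6 samples called 21% and 88%. The simulation changed few genes and gave all groups the same spread per gene. These rates therefore need not hold for the measured double line against wild type at SD2, with 4899 calls. Camera called a simulated group of 20 genes raised 2-fold and did not call 20 random genes. The simulated genes were drawn independently of each other, so this does not test the preset correlation. The run step recovered 98.0% of a run of 200 genes with 0 others.

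Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, the replicate number as a block, a fit of the 2 groups alone, leaving out each library in turn, and, for gene groups, fry and an estimated correlation. Genes outside the runs, a fit without the double-line SD2 libraries and all alternatives for the overlap were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.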

Results

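Gene expression was measured by RNA sequencing in leaves of oilseed rape, Brassica napus, of the cultivar Westar. Wild-type plants were compared with a CRISPR-edited line carrying a mutant BnaA06FAH gene (the single line) and with a line mutant in both BnaA06FAH and BnaC05FAH (the double line). These genes encode fumarylacetoacetate hydrolase, the last enzyme of tyrosine degradation, and the study asks what accompanies cell death when this enzyme is lost in short days. Leaves were sampled in long days (LD) and 1 day and 2 days after transfer to short days (SD1 and SD2), which gave 9 groups of 3 libraries and 27 libraries in all. Total counts ranged from 49700646 to 58862542 per library, and 70172 to 73495 genes had at least 1 count. Of 72039 genes with enough counts to be tested, 477 carry a gene name, so the genes named below are a small part of each count. The FAH genes are not analysed here, and the genotype labels were not checked through them. The labels do not say that the replicates came from separate plants, so the p-values measure only the spread between these samples, which may be technical. The labels give LD and SD plants the same light period and call the lines both knock-downs and null mutants, and the group names are used here as given.

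The first principal component of the 5000 most variable genes held 36.1% of the variance and set the 9 single-line libraries, between -137 and -114, apart from the 18 others, between 43.6 and 89.96. The second component, with 17.1%, ran from wild-type LD libraries, at -49.1 or lower, to the double line at SD2. Replicates 1 and 3 of the double line at SD2 lay at 117 and 124, and replicate 2 lay at -5.43, among the SD1 libraries. That library is named below beside the genes it sets.

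**Figure D1:**
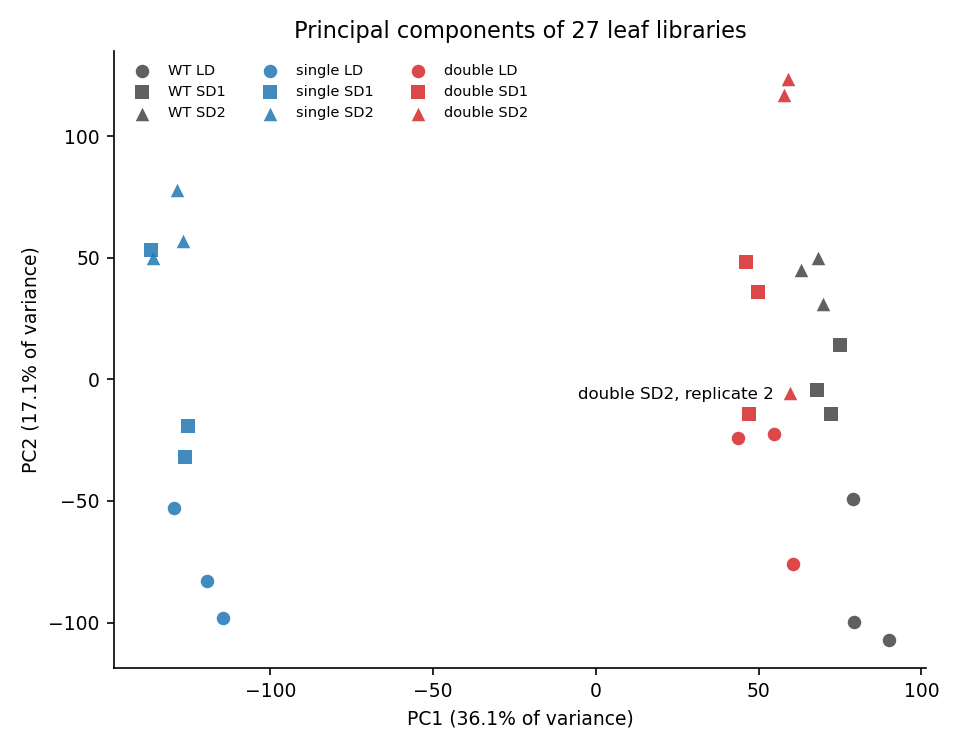
Scores of the 27 libraries on principal components 1 and 2 (horizontal and vertical axes, in units of the score, with 36.1% and 17.1% of the variance), with 1 point per library, coloured by genotype and shaped by stage. The single line stands apart on component 1, and double-line SD2 replicate 2 lies at -5.43 on component 2, against 117 and 124 for the other double-line SD2 libraries.

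Wild-type leaves were compared between stages, with no long-day group sampled on the same days, so age and sampling day are not parted from day length. After 2 short days, 6 of 16 genes of phenylpropanoid and flavonoid synthesis were called lower than in long days. The chalcone synthase CHSB1 (LOC106367233) fell from 39.9 ± 15.2 to 1.78 ± 0.949 normalised counts-per-million (CPM, mean ± SD, n = 3; log2 fold change -4.49 ± 0.90 SE, edgeR adjusted p = 0.0134). A second chalcone synthase gene, Chs (LOC106372253), fell from 21.3 ± 10.6 to 1.60 ± 0.701 CPM, by 3.74 on the log2 scale (adjusted p = 0.0221). The phenylalanine ammonia-lyase PAL-BN-1 (LOC106391500), which opens the pathway, fell from 32.0 ± 4.66 to 7.22 ± 1.61 CPM (adjusted p = 0.00554), and the cinnamate hydroxylase C4H (LOC106348398) fell from 9.96 ± 1.68 to 2.51 ± 0.436 CPM (adjusted p = 0.00396). In the family of 16 phenylpropanoid and flavonoid enzymes drawn up from gene names, 6 fell and none rose (camera adjusted p = 6.60e-04, and adjusted p = 0.0981 with an estimated correlation). The anthocyanin and flavonoid list, fixed before the data were examined, held 8 of the same genes without CHSB1 and C4H. In it 4 fell, and 5 did when adjusted over the list alone (camera adjusted p = 0.00679, and adjusted p = 0.162 with an estimated correlation). PAL1-2 (LOC106388514) and PAL2-2 (LOC106382579) were the other 2 called members, and F3H (LOC106367722) at log2 -1.26 and PAL2-1 (LOC106371449) at -0.04 did not pass. A second C4H gene (LOC106446415) stood at -0.53 with adjusted p = 0.192.

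Of 8 genes of nitrogen assimilation, 3 were called lower in the same wild-type libraries. The nitrate reductase NIA1 (LOC106400358) fell from 235 ± 88.0 CPM in LD to 33.3 ± 21.3 CPM at SD2, a log2 change of -2.82 ± 0.58 (edgeR adjusted p = 0.0139). NIA2 (LOC106368948), the other nitrate reductase named here, had already fallen at SD1, from 9.21 ± 1.16 to 1.23 ± 0.258 CPM (log2 -2.91, adjusted p = 0.0431), and stood at 2.58 ± 0.654 CPM at SD2 (adjusted p = 0.0452). The glutamine synthetase gene gln (LOC106424972), 1 of 3 so named, fell from 790.1 to 391 CPM at SD2 (adjusted p = 0.0200). Of the family of 8 nitrogen assimilation enzymes, 1 fell at SD1 (camera adjusted p = 0.00400, and adjusted p = 0.0355 with an estimated correlation). At SD2 3 fell (camera adjusted p = 0.00626, and adjusted p = 0.0781 with an estimated correlation).

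Other named genes rose in wild type at SD2. NAC69-1.1 (LOC106430127), a transcription factor of the NAC family, rose from 0.277 to 5.26 CPM (log2 4.25 ± 0.85, edgeR adjusted p = 0.0133). Raf23 (LOC106437717), a Raf-like kinase, rose from 13.8 to 37.1 CPM (adjusted p = 0.0236). CTR1 (LOC106372651), a Raf-like kinase that holds ethylene signalling off, rose from 9.37 ± 1.06 to 19.2 ± 3.52 CPM (adjusted p = 0.0105), and ABI1.1 (LOC106376079), a phosphatase that restrains abscisic acid signalling, rose from 27.4 to 68.7 CPM (adjusted p = 0.0155). CLIP (LOC106399593), BDC1 (LOC106348544) and the aminoalcohol phosphotransferase AAPT1 (LOC106436572) rose by 2.16, 1.74 and 1.47 on the log2 scale. Among kinases of mitogen-activated cascades, 5 of 34 rose (Raf23, CTR1, ZIK5, ZIK6 and MAPK7-1) and none fell (camera adjusted p = 0.00209, and adjusted p = 0.264 with an estimated correlation). Of 33 NAC genes 1 rose (camera adjusted p = 0.00157, and adjusted p = 0.260 with an estimated correlation). Of the CBL and CIPK calcium-signalling genes 1 of 24 rose, CIPK23.1 (LOC106390613; camera adjusted p = 0.0254, and adjusted p = 0.537 with an estimated correlation). Of 9 abscisic acid genes 1 rose, ABI1.1 (camera adjusted p = 0.0459, and adjusted p = 0.334 with an estimated correlation). CesA4.2 (LOC106410419), a cellulose synthase of secondary walls on the fixed list of vascular markers, fell from 7.43 to 1.58 CPM (log2 -2.23, adjusted p = 0.0112). The 3 other members of that list did not pass, CesA4.1 at log2 -1.82 (adjusted p = 0.0536), CesA7.1 at -1.21 (0.0520) and CesA8.1 at -1.88 (0.0675). BPL1 (LOC106439876) and the boron transporter BOR1 (LOC106392337) fell by 2.78 and 2.75.

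In all, 4229 genes passed between wild-type SD2 and LD, 2318 higher and 1911 lower, and 81 between SD1 and LD, 57 higher and 24 lower. The SD2 count was 82 without SD2 replicate 1, 939 without SD2 replicate 3, 536 without LD replicate 2 and 37 without LD replicate 3, and DESeq2 called 8668 genes. The SD1 count was 1328 without LD replicate 1 and between 4 and 19 without any other library of the comparison (5 without LD 2, 6 without LD 3, 19, 12 and 4 without SD1 replicates 1, 2 and 3), 4 in a fit of the 6 libraries alone, 2354 with DESeq2 and 173 when the double-line SD2 libraries were left out of the fit. C4H (LOC106348398) and PAL-BN-1 kept their calls under all 12 alternatives. CHSB1, Chs and NIA1 lost theirs without SD2 replicate 1, SD2 replicate 3 or LD replicate 3, with edgeR adjusted p up to 0.0772, 0.114 and 0.0796. CTR1, CLIP, NAC69-1.1 and CesA4.2 lost theirs without SD2 replicate 1 or LD replicate 3, with adjusted p up to 0.0688, 0.0712, 0.0877 and 0.0657. Raf23, ABI1.1, gln, BDC1 and AAPT1 lost theirs without SD2 replicate 1 or LD replicates 2 or 3 (adjusted p up to 0.132, 0.0964, 0.110, 0.117 and 0.0953), and Raf23 and gln also without SD2 replicate 3. BOR1 moved from -2.75 to -1.58 without LD replicate 1 (highest adjusted p = 0.120), and lost its call without any library but LD replicate 2. PAL1-2 and BPL1 lost theirs without any library but LD replicate 1, and NIA2 without any of the 6 at SD2 and without any but LD replicate 1 at SD1 (adjusted p up to 0.166, 0.136, 0.140 and 0.215). ZIK5 and MAPK7-1 lost theirs without SD2 replicate 1 or LD replicate 3, and MAPK7-1 also without LD replicate 2 or SD2 replicate 3 (up to 0.0902 and 0.0953). CIPK23.1 lost its call without any library but SD2 replicate 2 and in a fit of the 6 libraries alone (up to 0.199). At SD1, camera also found the phenylpropanoid family lower with 0 of 16 called (adjusted p = 0.00400, and adjusted p = 0.163 with an estimated correlation) and the anthocyanin list lower with 0 of 8 called, 5 when adjusted over the list alone (adjusted p = 0.00528, and adjusted p = 0.163 with an estimated correlation). With 0 genes called in each, the camera test at SD1 was positive for plastid-encoded photosystem, WRKY and mitogen-activated cascade genes and negative for the glucosinolate and myrosinase family (adjusted p = 0.0108, 0.0126, 0.0126 and 0.0362). None of these 4 passed with an estimated correlation (adjusted p = 0.548, 0.451, 0.448 and 0.311) or with fry (adjusted p = 0.224, 0.134, 0.107 and 0.0575).

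**Figure D2:**
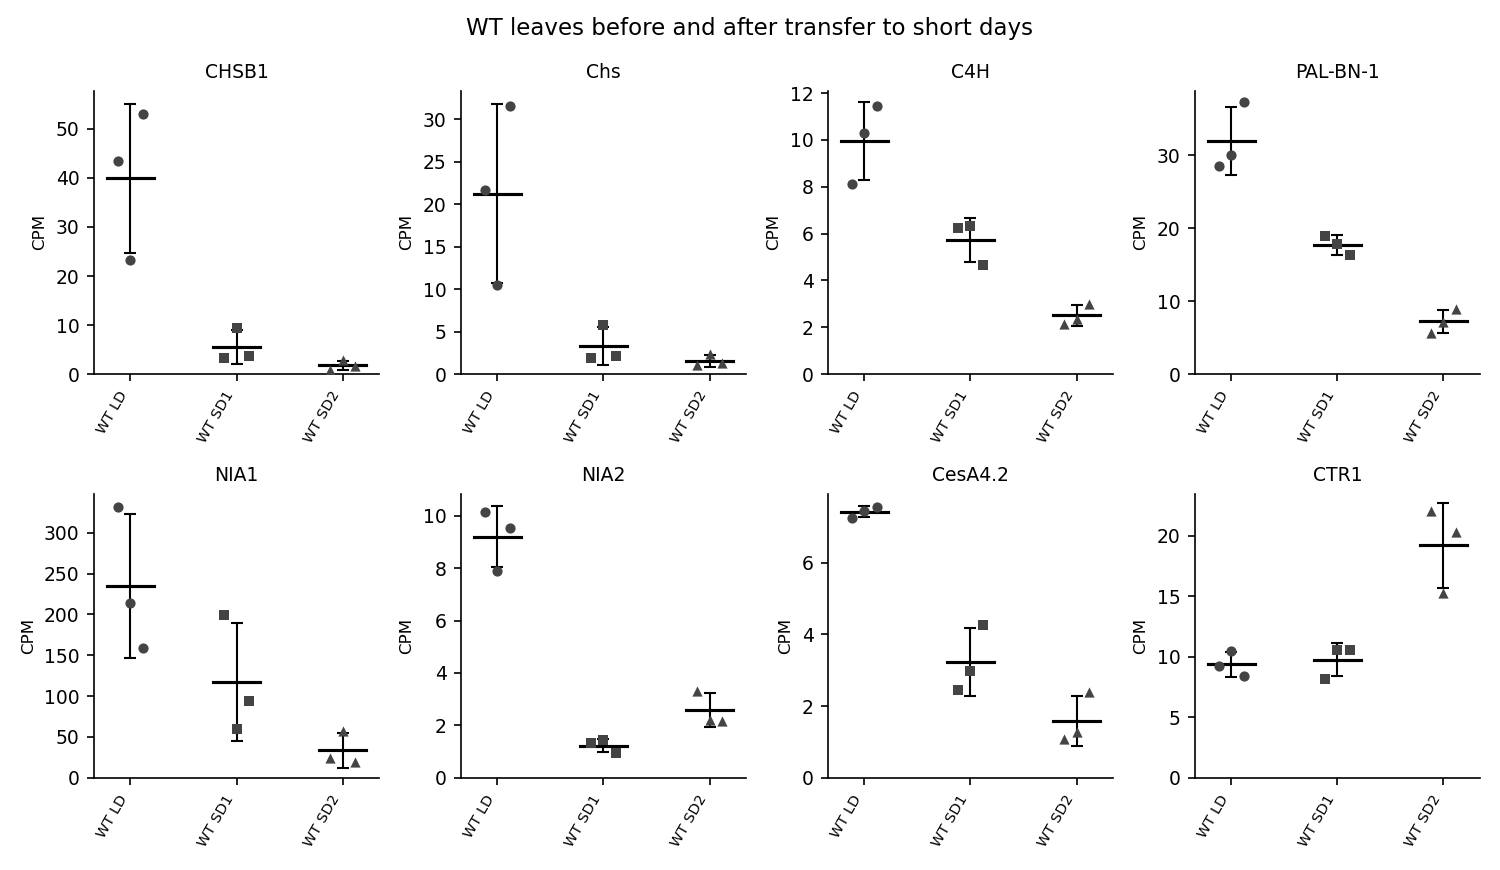
Normalised counts-per-million (vertical axes) of 8 genes in wild-type leaves in LD, SD1 and SD2 (horizontal axes), with points for single libraries and bars for the mean ± SD of 3 libraries. CHSB1 went from 39.9 to 1.78, PAL-BN-1 from 32.0 to 7.22, NIA1 from 235 to 33.3 and CTR1 from 9.37 to 19.2 CPM between LD and SD2.

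The double line was compared with wild type at each stage, and SD2 is the stage with the most genes called. BiP (LOC106345946), a chaperone of the endoplasmic reticulum, stood at 244 ± 154 CPM in the double line and 29.13 ± 13.7 CPM in wild type (n = 3 each; log2 fold change 3.07 ± 0.60 SE, edgeR adjusted p = 0.00478). Crt1 (LOC106415836), a calreticulin that works beside it, stood at 113 ± 54.9 against 22.4 ± 9.87 CPM (log2 2.34 ± 0.48, adjusted p = 0.00631). The myrosinase-associated protein gene MyAP1 (LOC106348442), of the glucosinolate defence system, rose to 1706 ± 1141 from 138 ± 85.6 CPM (log2 3.63 ± 1.07, adjusted p = 0.0447). The allene oxide cyclase AOC3.1 (LOC106437957), an enzyme of jasmonate synthesis, rose to 7.63 ± 6.85 from 0.482 ± 0.384 CPM (log2 3.98 ± 0.98, adjusted p = 0.0191). Its double-line and wild-type libraries overlapped, and it is given as the member of the jasmonate list. LSC222 (LOC106360896) rose to 42.5 ± 9.19 from 4.85 ± 2.67 CPM (log2 3.13 ± 0.61, adjusted p = 0.00484).

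Other named genes were lower in the double line at SD2. PIP2 (LOC106392705), a plasma-membrane aquaporin, fell to 7.83 ± 1.90 CPM from 68.0 ± 47.8 CPM in wild type (log2 -3.12 ± 0.47, edgeR adjusted p = 4.37e-04). SUT2-1 (LOC106400948), a sucrose transporter, fell to 9.77 ± 11.2 from 55.8 ± 15.9 CPM (log2 -2.52 ± 0.70, adjusted p = 0.0348). BRI1 (LOC106349513), the brassinosteroid receptor, fell to 7.21 ± 3.07 from 27.4 ± 9.49 CPM (log2 -1.92 ± 0.36, adjusted p = 0.00332). CTR1, which rose in wild type, stood at 8.87 ± 1.51 against 19.2 ± 3.52 CPM (log2 -1.12 ± 0.18, adjusted p = 0.00105). Of the calcium-linked kinases, CIPK14.1 (LOC106435460) fell by 1.40 (adjusted p = 0.00322) and CPK30.1 (LOC106354405) by 1.55 on the log2 scale (adjusted p = 0.00937), while CPK4.1 (LOC106438489) rose by 1.56 (adjusted p = 5.94e-04). CPK4.1 lies in the run of A3 genes that was higher in the double line at every stage, described further on. A few named genes were picked after their values were seen. Of these, catalase (LOC106358221), which removes hydrogen peroxide, fell to 493 ± 238 from 1072 ± 269 CPM (adjusted p = 0.0329). The blue-light receptors cry1 (LOC106429586) and cry2 (LOC106424300) fell by 0.98 and 0.88 on the log2 scale (adjusted p = 0.0116 and 0.0267), and RGA (LOC106445425), a DELLA repressor of gibberellin responses, fell by 1.06 (0.0245). The annexin gene Ann1 (LOC106347720) rose by 1.64 (adjusted p = 0.0325), and AGL20 (LOC106438253), a flowering-time gene, by 1.55 (0.0415), with a second AGL20 gene (LOC106450890) at 0.54 (0.701).

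The gene groups of the design gave these counts for the double line against wild type at SD2. On the list of cell death regulators the 1 member measured, the Bax inhibitor gene BI-1 (LOC106381875), stood at log2 0.73 with edgeR adjusted p = 0.0959. Of the senescence list, NAC29.1 (LOC106354073) fell by 3.77 (adjusted p = 0.0326) at no more than 1.58 CPM, and WRKY53 (LOC106375988) and WRKY53-1 (LOC106441470) stood at 2.19 and 2.63 without passing (0.151 and 0.0954). Of the salicylate list none of 3 passed, with NPR1 (LOC106376076) at 0.21, WRKY70 (LOC106367975) at 0.16 and WRKY70-1 (LOC106368083) at -0.47. The ethylene enzyme acs6 (LOC106372084) stood at -0.22, the tocopherol enzyme gene VTE4 (LOC106406285) at -0.12 and the heat shock cognate Hsc70 (LOC106361615) at 0.48, and none of them passed. AOC3.1 was the 1 member of the jasmonate list. On the anthocyanin list 0 of 8 passed, and 0 when adjusted over the list alone, with a median of 0.29 and a mean of -0.21. Of the glucosinolate and myrosinase family 2 of 8 rose, MyAP1 and the nitrilase Nit2 (LOC106437374), and of the glucosinolate list CYP83B1-5 (LOC106372082) stood at 1.72 (adjusted p = 0.0547), CYP79F1 (LOC106367453) at 3.43 (0.383) and CYP83A1-5 (LOC106430121) at 0.10 (0.960). The ribosomal protein gene RPS6 (LOC106373247) stood at 0.91 (adjusted p = 0.167). WRKY25-1 (LOC106407015) and WRKY26-1 (LOC106422600) rose by 2.08 and 1.74, and WRKY74-1 (LOC106348780) fell from 0.364 CPM to 0 in all 3 libraries, so that 2 of 30 WRKY genes were higher and 1 was lower. Among kinases of mitogen-activated cascades, 1 of 34 rose and 5 fell, CTR1, Raf29.1, ZIK5, MKK3.1 and MAPKKK20.1. Of the CBL and CIPK genes 2 of 24 fell, and of 12 CPK genes 3 rose and 1 fell. No group of the 24 tested passed camera in this comparison, and the smallest adjusted p was 0.139, for the CBL and CIPK genes.

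At SD2 4899 genes passed between the double line and wild type, 2514 higher and 2385 lower, and 38 of the 477 named genes were among them. The count rose to 13280 without double-line replicate 2 and fell to 1126 without double-line replicate 1, 1163 without replicate 3, 1293 without wild-type replicate 1 and 1533 without wild-type replicate 3. It was 272 in a fit of these 6 libraries alone and 9029 with DESeq2. Replicate 2 of the double line held 66.3 CPM of BiP against 333 and 333 in replicates 1 and 3, 50.4 of Crt1 against 138 and 151, 399.8 of MyAP1 against 2207 and 2510, 0.667 of AOC3.1 against 14.4 and 7.86, 22.7 of SUT2-1 against 4.45 and 2.18, and 748 of catalase against 277 and 453. For PIP2 it held 9.83 CPM against 7.61 and 6.06. CHSB1 stood at 29.3 CPM in replicate 2 and at 5.19 and 3.65 in the others. Its mean was higher in the double line (log2 2.84, edgeR adjusted p = 0.0462), and without replicate 2 it stood at 1.31 with adjusted p = 0.263. LSC222 passed under all 11 alternatives, and BiP, Crt1, PIP2, BRI1, CIPK14.1, CTR1, Raf29.1 and CPK4.1 passed whichever single library was left out and lost their calls in the fit of the 6 libraries alone (adjusted p up to 0.106). SUT2-1, catalase, RGA, cry2, WRKY74-1 and NAC29.1 lost their calls without replicates 1 or 3 of either genotype (adjusted p up to 0.176, 0.210, 0.124, 0.189, 0.146 and 0.197). MyAP1, Ann1, WRKY25-1, WRKY26-1 and Nit2 lost theirs without any library but double-line replicate 2 (adjusted p up to 0.174, 0.193, 0.128, 0.242 and 0.169). ZIK5 was lost without wild-type replicate 1 or double-line replicate 3 (up to 0.101). AOC3.1 was lost without wild-type replicate 1 or double-line replicates 1 or 3, and cry1 and CPK30.1 without double-line replicates 1 or 3 (adjusted p up to 0.132, 0.146 and 0.127). AGL20 (LOC106438253) was lost without any single library of the 6 (highest adjusted p = 0.144).

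**Figure D3:**
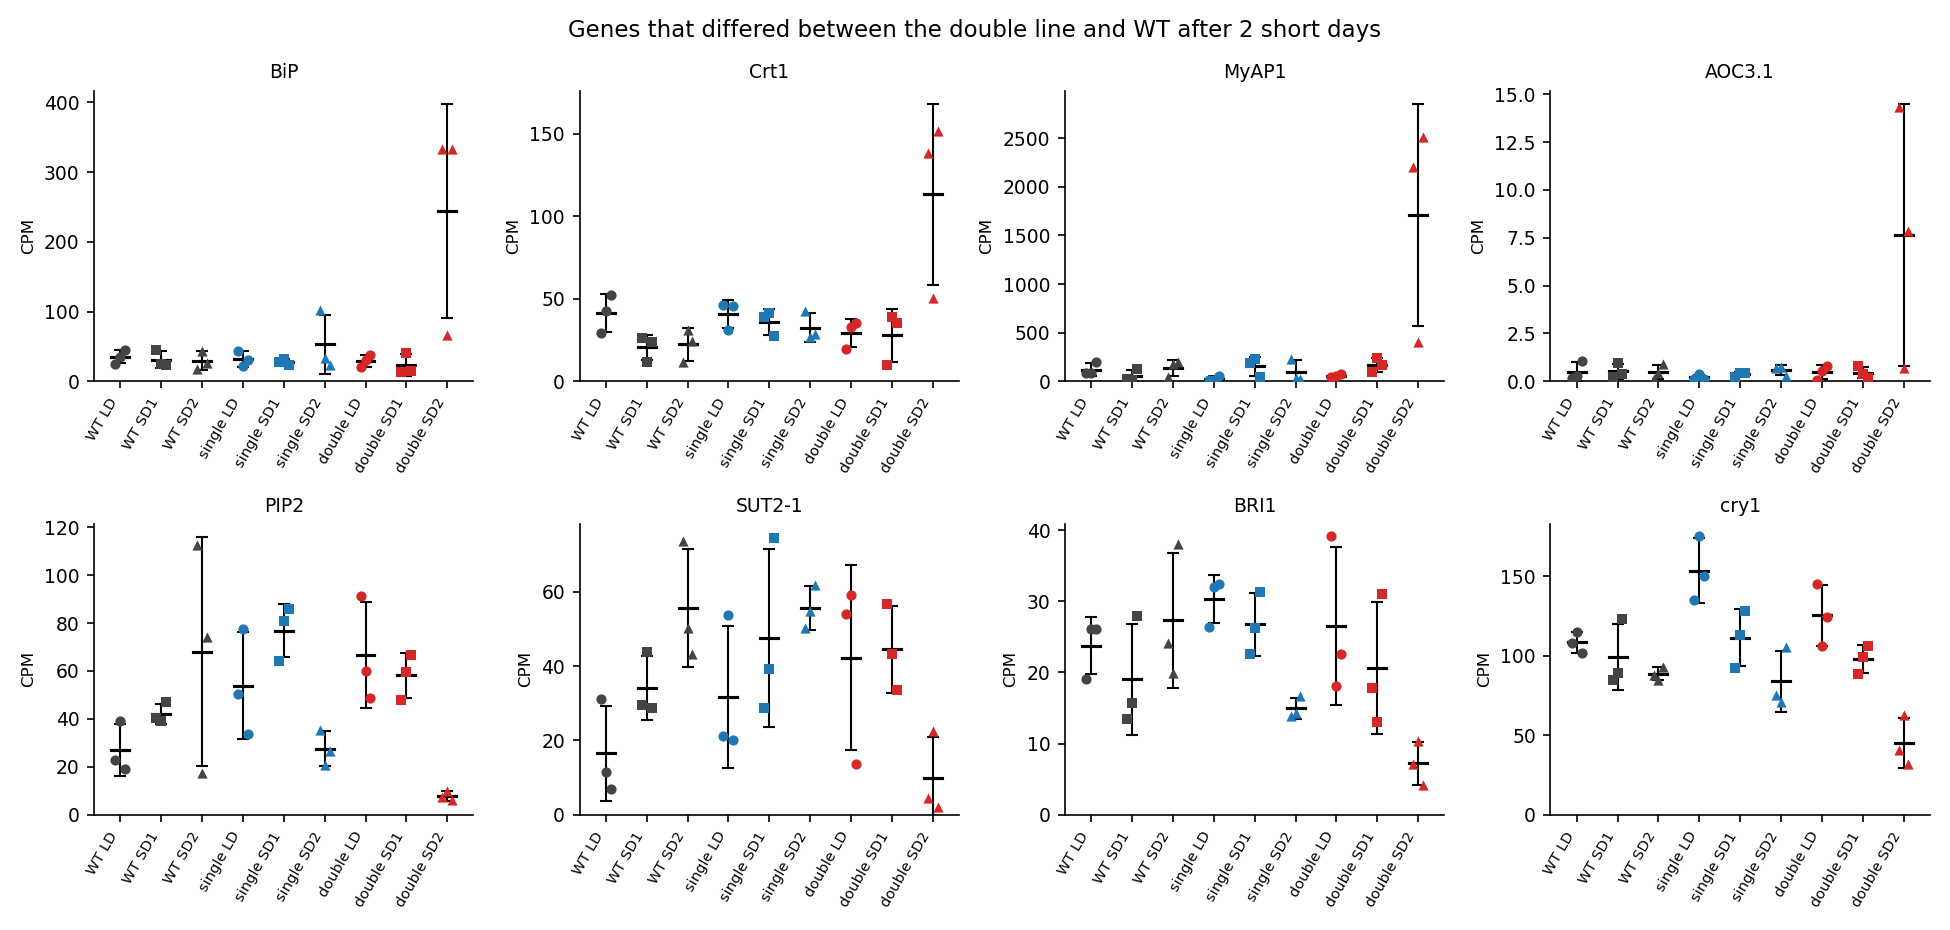
Normalised counts-per-million (vertical axes) of BiP, Crt1, MyAP1, AOC3.1, PIP2, SUT2-1, BRI1 and cry1 in the 9 groups of genotype and stage (horizontal axes), with points for single libraries and bars for the mean ± SD of 3 libraries. At SD2 the double line stood at 244 CPM for BiP against 29.13 in wild type, and at 7.83 CPM for PIP2 against 68.0.

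Whether the double line responded to short days differently from wild type was tested as the difference between their SD2 against LD changes. BiP went from 29.2 to 244 CPM in the double line and from 35.1 to 29.13 CPM in wild type, a difference of 3.33 ± 0.81 on the log2 scale (edgeR adjusted p = 0.0256). Crt1 went from 29.3 to 113 CPM against 41.4 to 22.4 CPM (2.84 ± 0.66, adjusted p = 0.0234). PIP2 went the opposite way in each genotype, from 66.6 to 7.83 CPM in the double line and from 27.05 to 68.0 CPM in wild type (-4.42 ± 0.63, adjusted p = 0.00585), and kept its call under all 16 alternatives. SUT2-1 went from 42.3 to 9.77 CPM against 16.5 to 55.8 CPM (-3.87 ± 0.97, adjusted p = 0.0280), and BRI1 from 26.6 to 7.21 against 23.7 to 27.4 CPM (-2.09 ± 0.50, adjusted p = 0.0248). For AOC3.1 the difference did not pass, with log2 values of 2.87 to 4.86 when 1 library was left out (edgeR adjusted p up to 0.258). The transcription factor genes MYB44 (LOC106358308), MYB77.1 (LOC106390878) and MYB73.1 (LOC106426812) differed by 2.78, 2.55 and 2.17, and MYB44 stood at 5.04 and 23.5 CPM in LD and SD2 of the double line and 35.2 and 23.9 CPM in wild type. Of 14 MYB genes 3 had a higher difference and none a lower one (camera adjusted p = 0.351). Among kinases of mitogen-activated cascades 8 of 34 had a lower difference and none a higher one, among them ZIK5 (LOC106346887) at -1.58 and CTR1 at -1.20 (camera adjusted p = 0.00302, and adjusted p = 0.638 with an estimated correlation). The CBL and CIPK genes had 2 of 24 lower, CIPK14.1 at -1.47 and CIPK2.1 (LOC106446097) at -1.24 (camera adjusted p = 0.0162, and adjusted p = 0.638 with an estimated correlation). Carotenoid enzymes had 1 of 9 lower, the zeaxanthin epoxidase ZEP (LOC106358361) at -1.25 (camera adjusted p = 0.0162, and adjusted p = 0.669 with an estimated correlation). The glucosinolate and myrosinase family had 0 of 8 called and a positive camera test (adjusted p = 0.0162, and adjusted p = 0.494 with an estimated correlation).

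This difference passed for 4446 genes, 2497 higher and 1949 lower. The count was 10643 without double-line SD2 replicate 2 and 6843 without double-line LD replicate 3. It was 16 and 80 without double-line SD2 replicates 1 and 3, 27 and 1899 without double-line LD replicates 1 and 2, 97 and 189 without wild-type SD2 replicates 1 and 3, and 1547 and 10 without wild-type LD replicates 2 and 3. DESeq2 called 8213. BiP, Crt1, BRI1 and MYB44 each lost the call without 6 of the 12 libraries, wild-type SD2 replicates 1 and 3, wild-type LD replicate 3, double-line LD replicate 1 and double-line SD2 replicates 1 and 3, with edgeR adjusted p up to 0.0908, 0.0849, 0.0956 and 0.0943. ZIK5 and CTR1 lost it without the same 6, MYB73.1 without these but wild-type SD2 replicate 3, and MYB77.1 without these and double-line LD replicate 2 (adjusted p up to 0.0697, 0.0726, 0.0623 and 0.0995). SUT2-1, CIPK14.1, CIPK2.1 and ZEP lost it without those 6 and wild-type and double-line LD replicates 2 (up to 0.0898, 0.0858, 0.125 and 0.118). At SD1 the double line's change from LD differed from that of wild type in 0 genes by edgeR, with 2822 genes at an unadjusted p under 0.05 and 45 genes by DESeq2. That count was 1 without wild-type LD replicate 2, wild-type SD1 replicate 2, double-line LD replicate 2 or double-line SD1 replicate 1, 2 without double-line LD or SD1 replicate 3, and 1 when the double-line SD2 libraries were left out of the fit. With 0 genes called in each, camera found a higher difference at SD1 for the glucosinolate and myrosinase family (adjusted p = 4.21e-04, and adjusted p = 0.0616 with an estimated correlation). It found a lower one for mitogen-activated cascades, plastid photosystem genes and carotenoid enzymes (adjusted p = 0.00367, 0.00367 and 0.0259, and adjusted p = 0.596, 0.674 and 0.674 with an estimated correlation).

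In long days the double line differed from wild type in 470 genes, 288 higher and 182 lower, and at SD1 in 407 genes, 254 higher and 153 lower. Raf33 (LOC106445806), a Raf-like kinase gene within the run of A3 genes, was higher at both stages, at 56.3 ± 2.80 against 22.1 ± 4.37 CPM in LD (log2 1.35, edgeR adjusted p = 1.61e-04) and at log2 1.02 at SD1 (adjusted p = 0.00426). MYB44 was lower at both, at 5.04 ± 1.80 against 35.2 ± 27.4 CPM in LD (log2 -2.80, adjusted p = 0.00624) and 6.98 ± 4.62 against 44.9 ± 6.68 CPM at SD1 (log2 -2.69, adjusted p = 0.00934). MYB73.1 was lower in LD, at 16.4 against 50.1 CPM (log2 -1.61, adjusted p = 0.00529). At SD1 WRKY70 and WRKY70-1, factors of salicylate responses, fell by 1.84 and 1.86 (adjusted p = 0.0403 and 0.0266), which is 2 of 3 on the salicylate list. These 2 genes carry the same name, so the share does not speak for the list. Of 14 MYB genes 1 was called lower at SD1, MYB44 (camera adjusted p = 0.0319, and adjusted p = 0.162 with an estimated correlation). The 5 ERF and DREB genes and the 12 plastid-encoded photosystem genes had 0 called (camera adjusted p = 0.0319 for each, and adjusted p = 0.179 and 0.650 with an estimated correlation). In LD 1 of 34 kinases of mitogen-activated cascades was higher, Raf33 (camera adjusted p = 9.12e-04, and adjusted p = 0.484 with an estimated correlation). The LD count was 291 without wild-type replicate 3, 305 without double-line replicate 1, 130 in the 6 libraries alone and 1188 with DESeq2. At SD1 it was 266 without wild-type replicate 2, 210 in the 6 libraries alone, 884 with DESeq2 and 271 when only genes outside the runs of neighbouring genes were tested. Raf33 was lost at both stages only in the 6 libraries alone (adjusted p up to 0.0729 and 0.105). MYB44 and MYB73.1 were lost in LD without wild-type replicate 3 or double-line replicate 1 (adjusted p up to 0.274 and 0.223 over all alternatives). The LD log2 value of MYB44 was -2.03 without wild-type replicate 3 and -3.24 without wild-type replicate 2. At SD1 MYB44 was lost without double-line replicates 1 or 3 (up to 0.0914), WRKY70-1 without any single library and WRKY70 without any but double-line replicate 1 (up to 0.192 and 0.217).

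**Figure D4:**
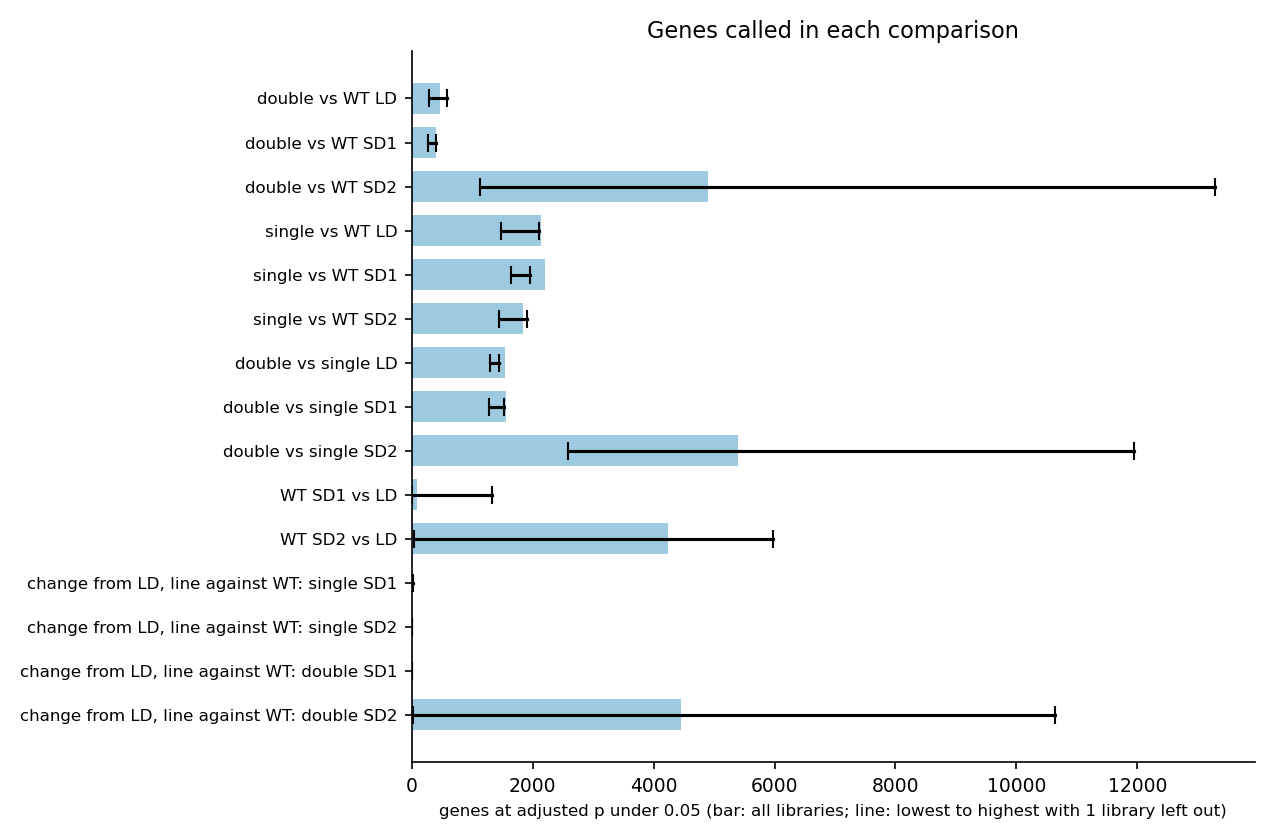
Genes with an edgeR adjusted p under 0.05 in each comparison (horizontal bars, number of genes), with lines from the lowest to the highest count when 1 library is left out. The double line against wild type had 470, 407 and 4899 genes in LD, SD1 and SD2, with 1126 to 13280 at SD2 on leaving out 1 library, and the single line had 2144, 2208 and 1845.

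Genes were placed in the gene order of the Da-Ae assembly of Brassica napus, since the authors' own build is not given in the sources used here, and the median fold change of 41 neighbouring genes was followed along each chromosome. In the single line a run of 1003 neighbouring tested genes on C8 had a median log2 fold change of -5.59 against wild type in LD, -5.59 at SD1 and -5.39 at SD2, with 706, 714 and 699 of them called lower. In the double line the medians of the same genes were 0.02, 0.03 and 0.03. A run of 605 genes on A8 was higher in the single line, with medians of 0.89, 0.95 and 0.95. The medians of the C8 run include genes at or near 0 counts in the single line, so their size is not a measured fold. Summed over the C8 run in LD, wild type held 15667 CPM and the single line 3242 CPM. The genes of the C8 run with at least 1 CPM in wild type had medians between -2.69 and -2.57 in the 9 single-line libraries. Those of the A8 run had medians between 0.81 and 0.89. In the double line a run of 335 genes on A3 was higher, with medians of 0.91, 0.93 and 0.88, and between 0.74 and 0.90 in its 9 libraries. Shorter runs on A9 were lower, of 43, 36 and 37 genes in the single line and 32 in the double line, and the 32 genes all lie inside the single line's runs. The run of 43 genes had LD medians of -5.56 in the single line (22 genes called lower) and -2.32 in the double line (13 called lower), and the run of 32 genes had -6.93 (20) and -4.89 (13). Genes near 0 counts enter these medians too. The summed LD counts of the 43 genes were 275 CPM in wild type, 74.5 in the single line and 142 in the double line. The runs were found on the LD libraries with a threshold chosen after the first results were seen, and the largest median in 100 shuffles of the gene order was 0.58 for the single line and 0.53 for the double line. Of the named genes, BSK2, TOC33, CPK10.1, CKX6-2 and PCNA lie in the C8 run, GAPDH.1 and NAC7.1 in the A8 run, and Raf33, CPK4.1, WRKY42, BOR and MYB12.1 in the A3 run.

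**Figure D5:**
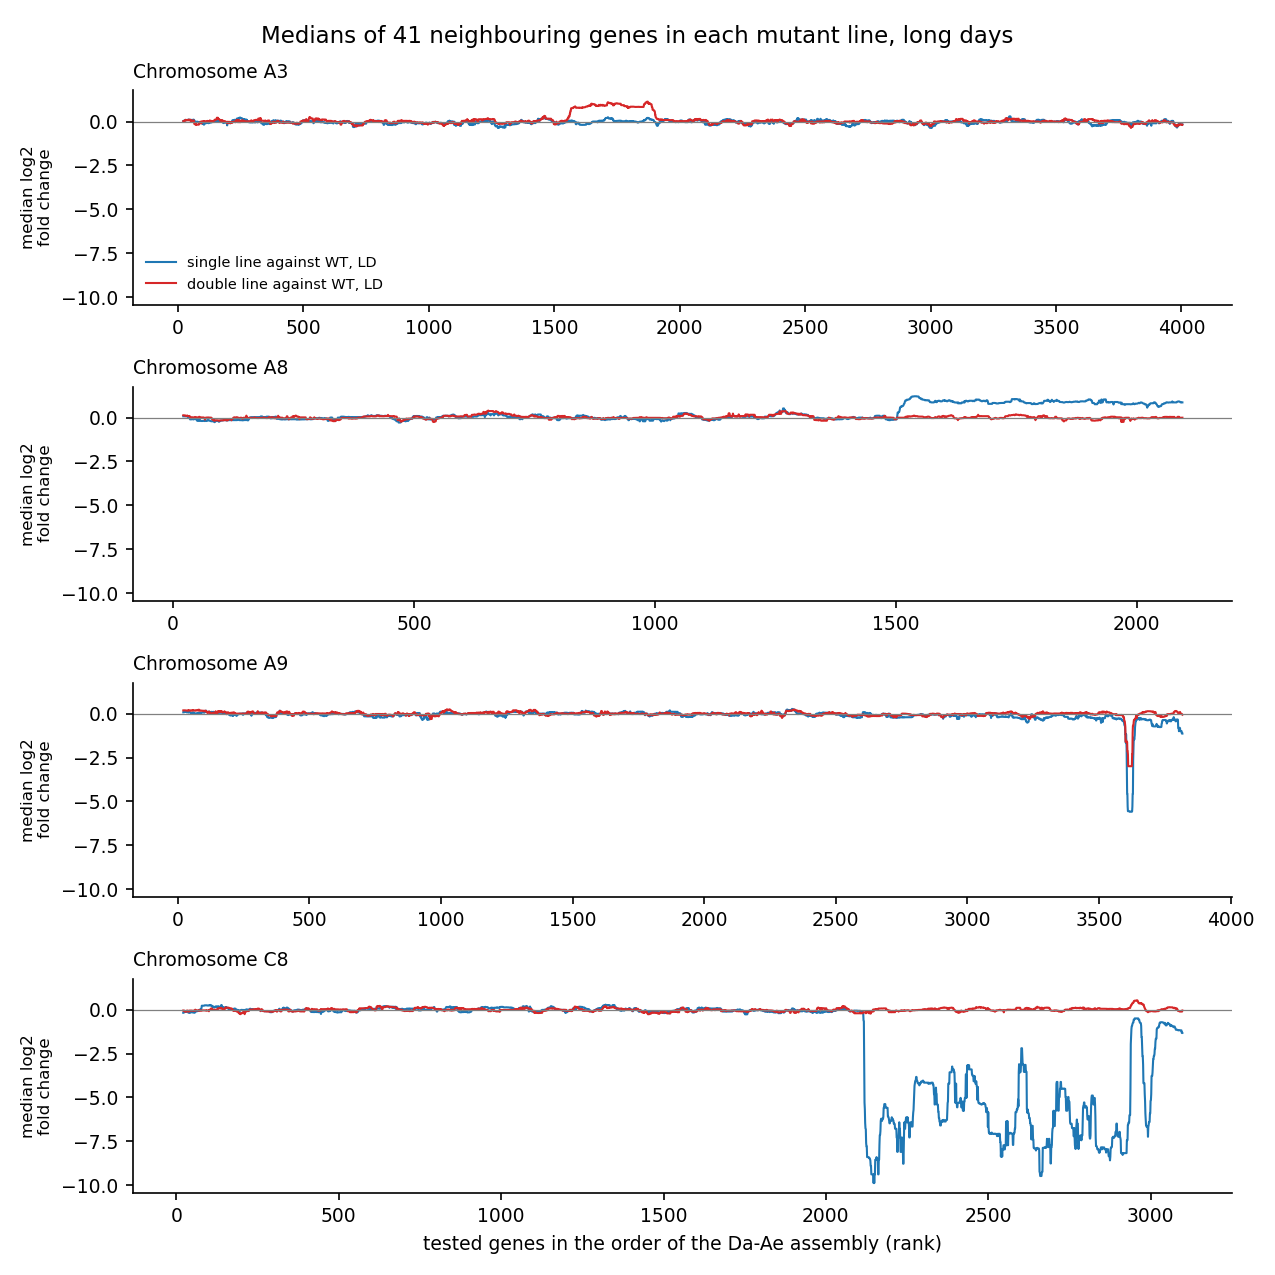
Median log2 fold change against wild type in LD (vertical axes) of 41 neighbouring genes along chromosomes A3, A8, A9 and C8 in the gene order of the Da-Ae assembly (horizontal axes, gene number), for the single line (blue) and the double line (red). The single line falls over a run of 1003 genes on C8 and rises over 605 genes on A8, and the double line rises over 335 genes on A3.

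The single line differed from wild type in 2144 genes in LD, 2208 at SD1 and 1845 at SD2, and 57.6%, 55.4% and 65.0% of those with a place in the gene order lay in the runs. BSK2 (LOC106416337), a kinase of brassinosteroid signalling in the C8 run, had no count in any of the 9 single-line libraries. Set against 3 counts per library, it was at least 159.7-fold, 167-fold and 182-fold lower than in wild type, where it stood at 10.02, 9.63 and 10.4 CPM. TOC33 (LOC106377345), a receptor of chloroplast protein import in the same run, fell to 14.0 ± 3.67 from 62.9 ± 14.3 CPM in LD (log2 -2.16, edgeR adjusted p = 2.97e-05). The calcium-dependent kinase CPK10.1 (LOC106368892), also there, fell by 2.82, 2.59 and 1.60 on the log2 scale in LD, SD1 and SD2. GAPDH.1 (LOC106382350), a glyceraldehyde phosphate dehydrogenase in the A8 run, rose by 1.06, 1.21 and 1.60 (adjusted p = 4.03e-04, 6.44e-05 and 1.21e-06). Of these calls, 1176, 1236 and 890 were genes outside the runs, genes without a place included. Of genes with a place, 713, 782 and 515 were called outside the runs. Among 139 genes with C8 in their identifier, 33 were called lower in LD. Genes without a place may therefore include genes of the runs, which would raise the counts outside them. When only genes outside the runs were tested and adjusted over, 806, 931 and 632 passed.

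Away from the runs, 6 of 30 WRKY transcription factor genes were called lower in the single line at SD1 and none higher, and the group did not pass (camera adjusted p = 0.392). WRKY70, at 17.4 ± 0.799 against 106 ± 8.43 CPM, fell by 2.61 (edgeR adjusted p = 2.90e-04). WRKY53-1, at 0.793 ± 0.320 against 17.3 ± 5.39 CPM, fell by 4.45 (adjusted p = 0.0151). WRKY70-1, WRKY53, WRKY40-1 (LOC106430771) and WRKY33-1 (LOC106410925) fell by 2.15, 4.37, 3.65 and 3.43. On the fixed lists this was 2 of 3 for salicylate (WRKY70 and WRKY70-1) and 2 of 3 for senescence (WRKY53 and WRKY53-1). Each pair carries the same name, so these shares do not speak for the lists. MYB44 fell by 2.50 (adjusted p = 0.00380), and the heme oxygenase HO1 (LOC106358404) rose by 0.65 (adjusted p = 0.0331). WRKY70, WRKY70-1 and MYB44 were also lower in the double line at SD1, against the same wild-type libraries. At SD2 NIA1 stood at 229.8 ± 36.2 CPM in the single line against 33.3 ± 21.3 in wild type (log2 2.79, adjusted p = 0.00465), and CTR1 was lower by 0.70 (adjusted p = 0.0342). The kinase MKK3.1 (LOC106391030) fell by 0.95 in LD (adjusted p = 0.0217) and 1.05 at SD2 (adjusted p = 0.0102), while in LD Raf23 rose by 1.33 (adjusted p = 0.0365) and MYB73.1 fell by 1.06 (0.0490). WRKY70, WRKY70-1 and MYB44 at SD1 and NIA1 at SD2 kept their calls under all 12 alternatives. Of the others, WRKY53-1 was lost without any of the 3 single-line SD1 replicates and WRKY53 without the first 2 of them (adjusted p up to 0.105 and 0.0731), WRKY40-1 without replicates 1 or 2 of either genotype (up to 0.128), and WRKY33-1 without any single library (up to 0.206). HO1 was lost without any library but wild-type replicate 3, CTR1 without wild-type replicates 1 or 3 or single-line replicates 1 or 2, and Raf23 without any wild-type replicate or single-line replicate 2 (up to 0.211, 0.255 and 0.326). MKK3.1 was lost in LD without wild-type replicate 2 or single-line replicates 1 or 3, and at SD2 without wild-type replicate 3 or single-line replicate 2 (up to 0.165 and 0.107). MYB73.1 was lost without any library but wild-type replicate 2 (up to 0.339). Of 9 carotenoid enzymes 0 were called in LD with a positive camera test (adjusted p = 0.0211, and adjusted p = 0.711 with an estimated correlation), and no group passed camera at SD1 or SD2 in this comparison.

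Whether the single line responded differently from wild type to short days was tested in the same way. At SD1 the change differed in 2 genes, LOC111210049 and LOC106415655, which have no name and are given because the count is so small (edgeR adjusted p = 0.00559 each). LOC106415655 lies in the C8 run and held 0.234 CPM in LD and 0 at SD1 in the single line against 7.52 and 8.402 CPM in wild type. LOC111210049 held at most 0.627 CPM in any wild-type group and none in the single line in LD, so no fold is given. The count was 12 without wild-type LD replicate 1, 8 without single-line LD replicate 3, 4 without single-line SD1 replicate 3, 1 when only genes outside the runs were tested and 199 with DESeq2. With 0 genes called in each, camera found a lower difference at SD1 for carotenoid enzymes, WRKY genes, plastid photosystem genes and the other plastid-encoded complexes, and a higher one for the glucosinolate and myrosinase family (adjusted p = 0.0149 for the first and 0.0330 for the others, and adjusted p = 0.638 to 0.688 with an estimated correlation). At SD2 it was 0 by edgeR, with 6185 genes at an unadjusted p under 0.05 and 155 genes by DESeq2. It was 3 without wild-type LD replicate 2 or single-line SD2 replicate 2, 4 without single-line SD2 replicate 3, 1 without single-line LD replicate 1 and 3 when the double-line SD2 libraries were left out of the fit.

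The 2 lines were compared with each other at each stage, and they differ in the runs of neighbouring genes as well as in the BnaC05FAH label. Named genes of the runs differed at all 3 stages. BSK2 was at least 168-fold lower in the single than in the double line at LD and SD1, and 166-fold at SD2. CPK10.1 was higher in the double line by 3.47, 2.83 and 2.60 and TOC33 by 1.54, 2.16 and 2.15 on the log2 scale at the 3 stages, and GAPDH.1 was lower by 0.84 in LD (edgeR adjusted p = 0.00624). CPK4.1 was higher in the double line by 0.97 in LD and 0.93 at SD1 (adjusted p = 0.0244 and 0.0337) and Raf33 by 0.98 in LD (0.00146), while STO-2 (LOC106365696) was lower by 0.76 in LD (0.0483). At SD1 WRKY53-1, low in the single line, was higher in the double line by 4.02 (adjusted p = 0.0377). At SD2 MyAP1 stood at 1706 ± 1141 CPM against 94.6 ± 119 in the single line (log2 4.17, adjusted p = 0.0223). Its log2 value was 6.03 without single-line replicate 1 and 3.68 without single-line replicate 3. PIP2 stood at 7.83 against 27.6 CPM (log2 -1.82, adjusted p = 0.0135) and SUT2-1 was lower by 2.51 (adjusted p = 0.0306). BPL1 rose by 2.98 (adjusted p = 0.0189), and CPK30.1 fell by 1.25 (adjusted p = 0.0253). The gibberellin oxidase gene GA2ox6-1 (LOC106370917) was lower by 5.23 (adjusted p = 0.0245), and by 0.84 without single-line replicate 2 (adjusted p = 0.774, the highest over its alternatives). Its call was also lost without double-line replicates 1 or 3. Of 9 carotenoid enzymes 2 were lower and of 8 sugar phosphate and starch enzymes 1 was (camera adjusted p = 0.0240 for both, and adjusted p = 0.891 for both with an estimated correlation). The 1 sugar phosphate gene was GAPDH.1, which lies in the A8 run. In LD 2 of 12 CPK genes were higher, CPK10.1 of the C8 run and CPK4.1 of the A3 run (camera adjusted p = 0.0394, and adjusted p = 0.846 with an estimated correlation). In all 1538, 1550 and 5403 genes passed in LD, SD1 and SD2. Of those placed, 84.0%, 83.1% and 26.4% lay in the runs, and 198, 212 and 3210 genes lay outside them. With genes without a place included, 496, 506 and 4251 of the calls were outside them. When only genes outside the runs were tested and adjusted over, 347, 361 and 3463 passed. The SD2 count was 11941 without double-line replicate 2, 2616 and 2695 without its replicates 1 and 3, 3068 and 2587 without single-line replicates 2 and 3, 2344 in the 6 libraries alone and 8768 with DESeq2. MyAP1, SUT2-1 and CPK30.1 were lost without double-line replicates 1 or 3 or single-line replicates 2 or 3, SUT2-1 also without single-line replicate 1, PIP2 without double-line replicates 1 or 3 or single-line replicate 1, and BPL1 without single-line replicates 2 or 3 (adjusted p up to 0.108, 0.151, 0.178, 0.0819 and 0.102). GAPDH.1 in LD was lost without double-line replicate 1 (up to 0.0965), CPK4.1 in LD without any library but double-line replicate 3, CPK4.1 at SD1 without replicates 1 or 2 of either line, and STO-2 without any of the 6 (up to 0.150, 0.192 and 0.251). WRKY53-1 at SD1 was lost without any single-line replicate or double-line replicate 2, and stood at 2.38 without the last (up to 0.319).

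Genes called against wild type in the same direction in both lines numbered 144 higher and 104 lower in LD, 140 and 119 at SD1, and 165 and 225 at SD2, with 0, 0 and 19 called in opposite directions. Outside the runs the counts were 142 and 87, 136 and 106, and 148 and 189. Independent lists of these sizes would share 3.06 and 3.48 genes in LD, 2.09 and 3.43 at SD1, and 17.2 and 44.8 at SD2. Across genes, the covariance of the fold changes of the lines was 0.885, 0.871 and 0.752 at the 3 stages. This was above the 0.382, 0.388 and 0.390 of simulated unchanged groups that shared simulated wild-type libraries. The measured wild-type values were not held fixed in the simulations. The correlation of these fold changes was 0.477, 0.490 and 0.359, below the 0.504, 0.510 and 0.505 of the simulations. Outside the runs it was 0.558, 0.575 and 0.424, which is above the simulated values of all genes in LD and at SD1 and below at SD2. Groups of 3 wild-type libraries cannot be split with 2 on each side, so part of the excess may come from the shared controls. The shared count at SD2 was 203 and 218 without wild-type replicates 1 and 3, 252 and 258 without single-line replicates 1 and 2, and 233 and 239 without double-line replicates 1 and 3. DESeq2 gave 588, 517 and 774 shared genes at the 3 stages.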

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

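The tests of the C8 run and the genotype, library size and shared direction tests of the outlying library were chosen only after the result was seen. The groups, contrasts, fixed lists and the regroupings of libraries were chosen before the data were examined.

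A difference between genotypes in the change from long days to short days brought these results here, each by a test of the difference itself. At SD1 2 genes differed between the single line and wild type. At SD2 4446 genes differed between the double line and wild type. That count held 33 named genes, and only those followed through the alternatives are given here. Among these, the difference was 3.33 for BiP, 2.84 for Crt1, 2.78 for MYB44, 2.55 for MYB77.1, 2.17 for MYB73.1, 2.05 for RPS6 and 1.103 for BOR on the log2 scale. It was -4.80 for NAC29.1, -4.42 for PIP2, -3.87 for SUT2-1, -2.58 for NAC41.1, -2.30 for CLIP, -2.23 for CPK30.1, -2.09 for BRI1, -1.58 for ZIK5, -1.47 for CIPK14.1, -1.25 for ZEP, -1.24 for CIPK2.1, -1.20 for Raf33 and -1.20 for CTR1. BOR and Raf33 lie in the A3 run of the double line. PIP2 kept its call whichever library was left out. CLIP, CPK30.1 and Raf33 lost theirs, like BiP, without wild-type SD2 replicates 1 or 3, wild-type LD replicate 3, double-line LD replicate 1 or double-line SD2 replicates 1 or 3 (edgeR adjusted p up to 0.0936, 0.0748 and 0.0703). NAC41.1 lost its call without these 6 and wild-type LD replicate 2, RPS6 without these 7 and double-line LD replicate 2, and NAC29.1 without these 8 and wild-type LD replicate 1 (edgeR adjusted p up to 0.103, 0.123 and 0.150). BOR, with edgeR adjusted p = 0.0498, lost its call without any library but double-line SD2 replicate 2 and without the low-count filter (up to 0.153). BOR, RPS6 and NAC29.1 also lost theirs with the replicate number as a block.

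Genotype labels were redrawn within each stage 40 times out of 200 possible ways. For the 4446 genes, 1 of 40 draws, the real one, called as many and the highest other called 2707. No other draw reached that count. The draws also carry the difference between the genotypes, as given below, so they do not exclude chance. For the 2 genes of the single line at SD1, 4 of 40 called as many and the highest other called 579, so chance is not excluded for that count. For the counts of 0, of the double line at SD1 and the single line at SD2, 40 of 40 called as many, with highest others of 1471 and 28. Every draw reaches a count of 0, so these draws decide nothing about chance. Draws that call 579 and 1471 genes point to a structure of the samples. Labels redrawn apart in each stage carry the difference between the genotypes into the contrast, and no other structure was tested. With 6 libraries in 2 groups there are 10 splits, too few for a share under 0.05. The real split alone, 1 of 10, reached its count in each such comparison. The double line against wild type had 470, 407 and 4899 genes in LD, SD1 and SD2 with highest others of 350, 1 and 586. The single line had 2144, 2208 and 1845 with 3, 0 and 1, and the lines against each other 1538, 1550 and 5403 with 4, 2 and 2156. Wild-type SD1 and SD2 against LD had 81 and 4229 with 9 and 1.

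The C8 genes lower in the single line form 1 pattern. Loss of FAH function in both lines is argued against by a median of 0.0165 for the same genes in the double line. Library size or scaling is argued against by a median of -0.0113 over 2115 C8 genes outside the runs. A changed dosage of chromosome segments, as a hypothesis, needs every short-day library of the single line to be shifted, and the highest C8 median among these 6 was -2.58 and the lowest A8 median 0.84. The counts gained by the A8 run came to 84.0% of those lost by the C8 run. Reads assigned to the other homoeologue and an exchange of segments both give such a value, so it does not tell them apart. In wild-type and double-line libraries the medians of both runs lay between -0.0863 and 0.0280. This argues against an assignment of reads that acts alike in all libraries. An assignment confined to the single line and an exchange of segments cannot be told apart without DNA or reads. The genes of the A8 and C8 runs were not paired as homoeologues.

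The double-line SD2 replicate 2 that lies apart is another pattern; a wrong genotype label is argued against by its A3 run median of 0.82, and library size by its depth, 57.2 in million-count units, inside the range of the others. Its stage score, the median log2 distance from wild-type LD over the 4229 genes called in wild type, was 0.70, inside the 0.10 to 0.80 of the double-line LD libraries, as a long-day library under a wrong label needs. On principal component 1 it also lay inside these libraries, at 59.8 against 43.6 to 60.6. On component 2 it lay outside them, at -5.43 against -76.0 to -22.4. The same held for component 3 (68.1 against 16.3 to 64.5) and component 4 (-11.9 against -80.0 to -22.4). The score alone therefore does not settle this label. Of the genes called without this library, 72.2% stood in the same direction in it, which decides nothing, since the share ran from 36.4% to 58.0% in double-line LD, 53.9% to 77.3% in double-line SD1, 55.8% to 78.1% in single-line SD2, 57.0% to 61.8% in wild-type LD and 40.5% to 63.9% in wild-type SD2 libraries. The SD1 libraries of the double line had stage scores from 0.84 to 1.30, less than 1 SD (0.24) away, and its other SD2 libraries, at 1.06 and 1.11, lie inside that range, so the score does not part SD1 from SD2 in this line and a library of 1 short day cannot be told apart. A slower response to short days is a biological alternative that was not tested.

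Genes called the same way in both lines in LD, 229 outside the runs, are the last pattern. Chance values of the shared wild-type libraries are argued against, since 93.4% of them (214) had the same direction in both lines at SD1, against other wild-type libraries. Sequence or copy differences between the wild-type plants and both lines may add to it: 27.9% of the genes had 3 counts or fewer in every wild-type library (35 genes) or in every library of both lines (29 genes), against 1.96% of the genes called for the double line at SD2. Loss of BnaA06FAH, which both lines share, could give the 62.4% (143 genes) called the same way at all 3 stages, but a difference in background gives that as well, so these cannot be told apart here.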

How the results depend on the processing

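The alternatives outside the runs of neighbours, without the double-line SD2 group and all those for the overlap were chosen only after the result was seen. Counts of called genes kept within 1.5 times the main value in 15 of 15 contrasts with RLE size factors and 15 of 15 without a low-count filter. Of 156 named calls or examples, 155 were the same with RLE size factors, 143 without the filter and 149 with DESeq2, where 7 were gained. With 1 library left out, 46 of 114 counts moved and 430 of 1074 gene results lost significance, 9 gained it and 2 reversed. A group left with 2 libraries is assumed to vary like the others. In the fit of 6 libraries 54 of 132 gene results were lost. The shift in most counts with the choice of test is a limit on them, and the cause was not tested.

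With DESeq2 the double line against wild type had 1188, 884 and 9029 genes in LD, SD1 and SD2, the single line 3502 in LD and 2818 at SD2, and the lines against each other 8768 at SD2. Wild-type SD1 and SD2 against LD had 2354 and 8668. The differences in change had 199 (single, SD1), 45 (double, SD1), 155 (single, SD2) and 8213 (double, SD2), and the overlap of the lines 588, 517 and 774. In the fit of 6 libraries the double line had 130, 210 and 272 genes against wild type and 2344 against the single line at SD2, and wild-type SD1 against LD had 4. The single line against wild type had 1911, 2376 and 1822 there. In the main fit its called genes had median absolute log2 changes of 3.17, 3.46 and 3.71, against 1.41 for the double line at SD2. Changes of that size can pass with few samples, so these counts do not tell whether fewer samples account for the drop. Double-line SD2 replicate 2 had a chi-square per gene of 167 and 181 against replicates 1 and 3, which had 40.1 between them. The fit of 27 libraries shares 1 estimate of the spread across groups, so its p-values may understate the spread of that group. With only the genes outside the runs tested and adjusted over, the single line had 806, 931 and 632, the lines against each other 347, 361 and 3463, the double line 271 at SD1, and the single line's SD1 change 1. Without the double-line SD2 group, wild-type SD1 against LD had 173, the double line's SD1 change 1 and the single line's SD2 change 3. The cause was not tested for the DESeq2 values, for the fit of 6 libraries or for the values without that group.

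With the replicate block, wild-type SD1 against LD had 50 genes, and the double line against wild type 4077 at SD2; the cause was not tested. Of the 156 gene results 136 were the same, 19 lost significance and 1 gained it. Those lost include, for the double line at SD2, MyAP1, CHSB1, NAC29.1, WRKY26-1, CPK3-2.1 and AGL20, and for its SD2 change BOR, RPS6 and NAC29.1. WRKY70 was lost in the double line at SD1, Raf23 and MYB73.1 in the single line in LD, WRKY33-1 there at SD1, and WRKY53-1 at SD1 and GA2ox6-1 at SD2 between the lines. CesA4.1 was gained in wild type at SD2. The numbers do not pair the libraries: the mean correlation of 108 pairs of the same number was -0.00476 against 0.0023 for other numbers, and 9 of 27 libraries correlated best with one of their own number.

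Of the gene groups, with an estimated correlation 0 passed for the double line's SD2 change, 1 for wild-type SD1 and 0 for wild-type SD2. With fry 2 passed for the double line's SD2 change and 4 for wild-type SD1. Of 18 group results, 18 were the same with RLE size factors, 17 with the replicate block, 11 with fry and 1 with an estimated correlation, and the others lost significance. The group lost with the replicate block was abscisic acid signalling and synthesis in wild type at SD2 (adjusted p = 0.0522).

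With 1 library left out, the double line against wild type ranged from 291 to 587 genes in LD, 266 to 402 at SD1 and 1126 to 13280 at SD2, and the lines against each other from 2587 to 11941 at SD2. Wild-type SD1 against LD ranged from 4 to 1328 and SD2 from 37 to 5972. The changes ranged from 2 to 12 (single, SD1), 0 to 2 (double, SD1), 0 to 4 (single, SD2) and 10 to 10643 (double, SD2), and the overlap at SD2 from 203 to 565. For the double line at SD2, NPR1 (LOC106376076) was -0.0149 without double-line replicate 3 and up to 0.35 otherwise, and the VTE4 gene (LOC106406285) 0.0121 without double-line replicate 1 and down to -0.25. Neither passed in the main test, and the cause was not tested. Depth limits only genes of low count, since the spread between replicates exceeds counting noise.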

Other observations

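On leaving out double-line replicate 2, the setting that calls 13280 genes, 3 of the named genes followed through the alternatives that had not passed did so in the double line against wild type at SD2. With all libraries 4899 genes passed. The 3 gains thus come with a general rise in calls and were not shown to be particular to these genes. The Bax inhibitor gene BI-1 (LOC106381875) stood at log2 1.08 with edgeR adjusted p = 9.57e-04, against 0.73 and adjusted p = 0.0959 with all libraries, and did not pass under any other alternative (0.53 and adjusted p = 0.344 without double-line replicate 3). CYP83B1-5 (LOC106372082), an enzyme of glucosinolate synthesis, stood at 2.09 with edgeR adjusted p = 0.0104, against 1.72 and adjusted p = 0.0547. It also passed with DESeq2 (adjusted p = 0.0121) and under no other alternative (1.43 and edgeR adjusted p = 0.193 without double-line replicate 3). WRKY53-1 (LOC106441470) stood at 3.04 with edgeR adjusted p = 0.0420, against 2.63 and adjusted p = 0.0954, and also passed with DESeq2 (adjusted p = 0.0400) and under no other alternative (edgeR adjusted p up to 0.275).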
